A study of Mus musculus with 30 samples.

How the data were processed

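Total RNA from whole lungs of 30 C57BL/6 mice was labelled and hybridized to Affymetrix mouse expression arrays. The 8 groups cross 2 ages, 21 days and 16 weeks, with control, inhaled LPS, mechanical ventilation, and LPS followed by ventilation. The deposited values are summarised probe set intensity on a linear scale, already normalized between arrays by the authors, whose method of normalization is not stated. MAS5 is the only tool named in the submitters' processing notes. The values ran from 4.5 to 25073 with array medians of 21.6 to 22.8, and they lack the low tail usual of MAS5 signals, so the algorithm that summarised the probes is not settled. Fold changes of dim genes depend on it, and the background of the arrays is included in the intensities.

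Of 45037 probe sets, 34945 carried a single gene symbol in the platform's annotation, 932 carried several and 9160 were not listed there. Gene identifiers of 34741 of them were found in the RefSeq gene table, which was used for names only, and no symbol changed. A probe set was kept when its intensity was above the own array's median on at least 3 arrays, which left 24825 probe sets. Values were taken as log2(intensity + 32). Each gene was represented by the probe set with the highest mean, which gave 13089 genes tested of 18193 named. Of these, 5611 had several probe sets, and 1401 were measured by a probe set that may bind related transcripts.

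Linear models were fitted in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with an intensity trend), with 1 mean per group and a spread shared by all 8 groups (22 residual and 4.87 prior degrees of freedom). There were 16 comparisons: adult against juvenile control, 5 within each age (each treatment against control, and LPS+MV against LPS and against MV), the interaction of LPS and MV within each age, and the interaction of age with each treatment. Tests were two-sided and adjusted by Benjamini and Hochberg within a comparison, with a threshold of 0.05. Values named across an interaction are differences of log2 fold changes. Figures were drawn with matplotlib 3.10.9.

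The 24 gene lists, the comparisons, the threshold and the rule for named genes were chosen before the data were examined. For a treatment against control and for the controls, the rule names, of the genes that passed and whose groups did not overlap on any array, the 8 highest and the 4 lowest. For other comparisons it names the 5 highest and the 5 lowest genes that passed. For each list it names up to 4 members with the smallest p, and other list members may be named with their value. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over all 384 list tests. Of these, 159 passed, 23 passed with the correlation estimated from the data, and 109 passed with fry, which tests whether a list's genes move one way without comparing them with other genes. The 23 were cytokine and TLR genes with LPS or LPS+MV against control and with LPS+MV against MV at both ages, interferon-stimulated genes in these comparisons in juveniles, adhesion genes in these comparisons except juvenile LPS alone, antioxidant genes in juvenile LPS+MV against MV, and MHC class II and matrix genes between the controls. No list that passed had a median, mean and test of different sign.

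On simulated data with 200 of 13089 genes changed, the same model recovered 81.7% of log2 changes of 0.5 and 96.9% of those of 1 with 4 animals against 4, with 10 false calls among 193. With 3 against 4 it recovered 83.1% and 97.3%, with 8 false calls among 195, and 0 of 384 unchanged list tests passed. Alternatives tried were quantile normalization, a pseudocount of 1, no filter, the mean over a gene's probe sets, no intensity trend, array weights, only the compared groups in the fit, the replicate number as a block, and each array left out in turn. A term for the Xist pattern was added after the data were seen. So were fits without 4 arrays that stand apart or 2 with high heat shock genes. Control probe sets are not in the deposited table. Sex, litter, collection time and hybridization batch are not in the labels and were not used.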

Results

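RNA from whole lungs of C57BL/6 mice was measured on 30 arrays, 1 per animal. Juvenile mice were 21 days old and adult mice 16 weeks old. At each age, untreated animals that breathed spontaneously served as controls. Others inhaled an aerosol of lipopolysaccharide (LPS), a bacterial outer membrane component that triggers innate immunity, for 30 minutes, then breathed spontaneously for 2 h. Others received mechanical ventilation (MV) at a tidal volume of 15 mL/kg and 30% oxygen for 2 h. A last set inhaled LPS and was then ventilated (LPS+MV). Controls have no stated study period. There were 4 animals per group, except for 3 in the juvenile MV group and 3 in the juvenile LPS+MV group. The series asks whether the response of the lung to inhaled LPS, ventilation and their combination depends on age. The upper quartile of intensity lay between 89.1, on adult MV replicate 3, and 111. The number of arrays limits the precision. After filtering, 13089 genes were tested with limma, and a gene's value below is its log2 fold change ± the standard error (SE) of that fit, unless an intensity is named.

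The labels do not give the sex of the animals, and sex-linked transcripts split the arrays into 2 sets. Xist, transcribed from the inactive X chromosome, had an intensity of 425 to 771 on 11 arrays and of 18.2 to 27 on the other 19. The Y-linked gene Eif2s3y was at 5.84 to 10.1 on those 11 arrays and at 160 to 238 on the other 19. High Xist was seen in 1 of 4 juvenile controls, 1 of 3 juvenile MV, 0 of 4 juvenile LPS and 2 of 3 juvenile LPS+MV arrays. In adults it was seen in 0 of 4 controls, 4 of 4 MV, 0 of 4 LPS and 3 of 4 LPS+MV arrays, so treatment and this pattern overlap in adult comparisons of ventilated with unventilated animals. A fit with this pattern as a term was therefore tried for every comparison, after the markers were seen.

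**Figure D1:**
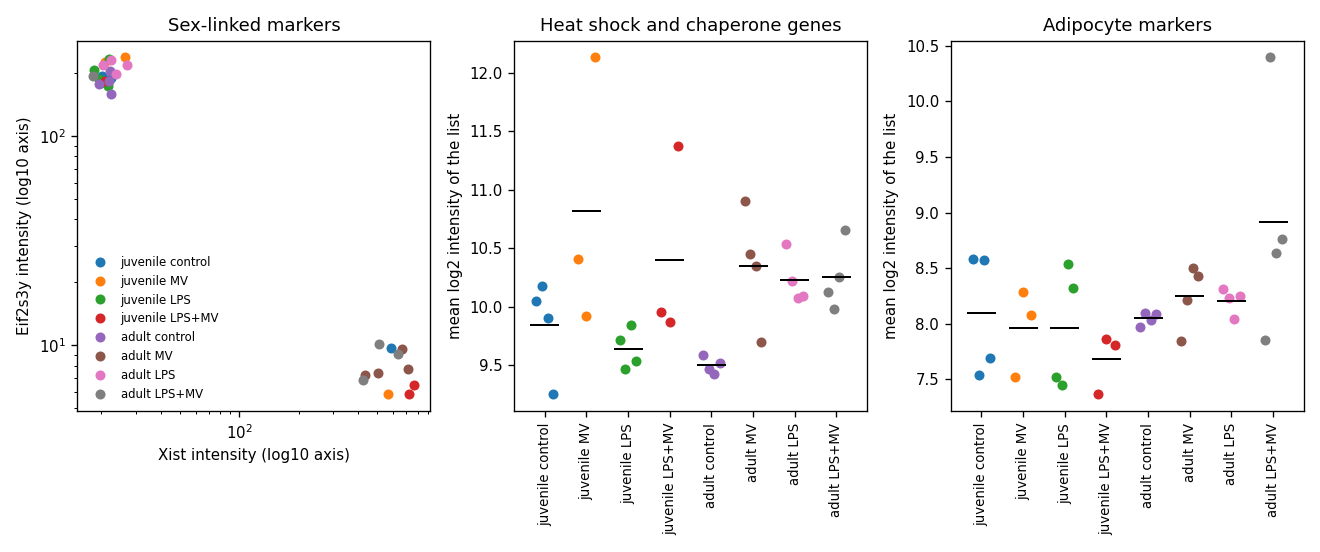
Left, Xist against Eif2s3y intensity on log10 axes for the 30 arrays. Middle and right, mean log2 intensity of the heat shock and adipocyte lists, with 1 point per array and a line at each group mean. Juvenile MV replicate 3 (12.1) and juvenile LPS+MV replicate 3 (11.4) lie highest for heat shock genes, and adult LPS+MV replicate 2 (10.4) for adipocyte markers.

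Untreated lungs of the 2 ages were compared first (4 arrays each). Elastin mRNA (Eln), which encodes the main protein of elastic fibres, had an intensity of 5387 ± 1115 (SD, n = 4) in juveniles and 955 ± 109 (SD, n = 4) in adults. Of the extracellular matrix genes, 17 of 20 were lower in adults, 1 was higher and 2 did not pass (18 lower and 1 higher adjusted within the list, median -0.89, camera adjusted p = 8.7e-17). They included Eln (-2.44 ± 0.18), the collagen genes Col5a2 (-1.25 ± 0.10) and Col3a1 (-1.10 ± 0.12), and Sparc (-0.67 ± 0.07), a matrix-binding glycoprotein. Of the cell cycle genes, 21 of 24 were lower in adults and 3 did not pass (22 lower adjusted within the list, median -0.65, camera adjusted p = 2.4e-11, 0.47 with estimated correlation). The median was -0.37 without juvenile control replicate 1 and -1.16 with a pseudocount of 1. They included the proliferation markers Mki67 (-1.32 ± 0.30) and Pcna (-0.63 ± 0.11). MHC class II genes, used for antigen presentation, were higher in 8 of 9 cases and not passed in 1 (9 higher adjusted within the list, median 0.79, camera adjusted p = 1.3e-10). They included H2-Eb1 (1.02 ± 0.10), H2-Ab1 (1.05 ± 0.12) and the invariant chain Cd74 (0.68 ± 0.08).

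Other immune transcripts were also higher in adult lungs. Of the T, B and NK cell markers, 11 of 18 were higher and 7 did not pass (13 higher adjusted within the list, median 0.43, camera adjusted p = 9.1e-05, 0.39 with estimated correlation). The antibody genes Jchain (2.18 ± 0.44) and Ighm (1.98 ± 0.44) and the granzyme Gzma (1.87 ± 0.49) lay among the 8 highest genes. Neutrophil markers were higher in 8 of 14 cases (10 adjusted within the list, median 0.95, camera adjusted p = 3.6e-04, 0.58 with estimated correlation), with a median of 0.62 without adult control replicate 4. They included Ltf (1.61 ± 0.25) and S100a8 (2.34 ± 0.52). TLR and NF-kB pathway genes were higher in 11 of 21 cases, lower in 0 and not passed in 10 (12 higher and 1 lower adjusted within the list, median 0.34, camera adjusted p = 4.6e-04, 0.5 with estimated correlation). They included Cd14 (0.60 ± 0.11), a co-receptor for LPS. The other highest genes were the airway secretory gene Bpifa1 (2.47 ± 0.48), Wfdc17 (2.35 ± 0.41), Il1b (2.24 ± 0.32), which encodes interleukin-1 beta, the monocyte chemokine receptor Ccr2 (1.91 ± 0.35), and Ifitm6 (1.89 ± 0.40). The 4 lowest were Cyp1a1 (-2.96 ± 0.61), a target of the aryl hydrocarbon receptor, Clca1 (-2.50 ± 0.75), Nrep (-2.42 ± 0.25) and Eln. Glucocorticoid and metallothionein genes were lower in 7 of 16 cases and not passed in 9 (8 lower adjusted within the list, median -0.62, camera adjusted p = 0.0027, 0.63 with estimated correlation). They included Zbtb16 (-2.21 ± 0.28) and Tsc22d3 (-1.27 ± 0.22). In all, 3301 genes differed, 1982 higher and 1319 lower in adults, and 175 of them by at least 2-fold. Groups did not overlap in 2310 of them and 22.1% of all genes tested (2.86% by chance). The Clca1 call ended without juvenile control replicate 3 (adjusted p = 0.085) and the glucocorticoid list call without juvenile control replicate 4 (adjusted p = 0.13, median -0.28) or with array weights (adjusted p = 0.065, median -0.39).

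Ventilation alone in juveniles (3 arrays against 4 controls) asks what ventilation without LPS changes. Flcn (1.10 ± 0.12) and its partner Fnip1 (1.11 ± 0.14), regulators of nutrient signalling at the lysosome, rose, and Tubb4b (-1.09 ± 0.09), a tubulin of cilia, fell. Of the immediate early and stretch-responsive genes, 10 of 28 rose and 18 did not pass (15 and 1 adjusted within the list, median 0.63, camera adjusted p = 6.4e-08, 0.49 with estimated correlation). Klf6 (0.72 ± 0.13) and Ccn2 (0.93 ± 0.20), a mechanosensitive matrix protein, were among the risers. Of the TLR and NF-kB pathway genes, 6 of 21 rose and 15 did not pass (7 and 0 adjusted within the list, median 0.20, camera adjusted p = 2.2e-05, 0.38 with estimated correlation). They included Tlr4 (0.55 ± 0.11), the LPS receptor, and Tnfaip3 (0.71 ± 0.15). The neutrophil granule gene Camp (1.08 ± 0.21) rose, as did Ngp (1.70 ± 0.54) and Clec4d (1.63 ± 0.38). Of the neutrophil markers, 2 of 14 rose and 12 did not pass (2 and 0 adjusted within the list, median 0.36, camera adjusted p = 0.0025, 0.64 with estimated correlation). Of the circadian clock genes, 5 of 14 rose and 9 did not pass (7 and 0 adjusted within the list, median 0.48, camera adjusted p = 3.7e-04, 0.16 with estimated correlation). They included Nr1d2 (1.19 ± 0.32), Per3 (0.62 ± 0.17) and Dbp (1.94 ± 0.56). The lowest genes beside Tubb4b were Slc25a37 (-1.26 ± 0.25) and Fech (-1.15 ± 0.22), which act in haem synthesis, and the red cell gene Bpgm (-1.05 ± 0.20). Alas2 (-1.0 ± 0.22), which starts haem synthesis in red cells, fell as well. Of the cell cycle genes, 0 of 24 rose, 4 fell and 20 did not pass (0 and 7 adjusted within the list, median -0.41, camera adjusted p = 3.0e-05, 0.69 with estimated correlation). They included Mcm6 (-0.63 ± 0.16). Medians moved with single arrays, to 0.39 for early-response genes without MV replicate 3, 0.33 and 0.11 for TLR genes without MV replicate 2 and control replicate 1, 0.60 for neutrophil markers without MV replicate 2, and -0.14 and -0.71 for cell cycle genes without control replicates 1 and 4.

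Of the heat shock and chaperone genes, 3 of 14 rose and 11 did not pass (5 and 0 adjusted within the list, median 0.75, camera adjusted p = 3.6e-05, 0.58 with estimated correlation). Hspa1a (3.05 ± 0.89), an inducible HSP70, rose, and juvenile MV replicate 3 had a mean log2 of 12.1 for this list against 9.92 and 10.4 on the other 2 arrays. Without that array the list call ended (adjusted p = 0.43, median 0.072, against 1.13 without replicate 2), and so did those of Hspa1a (adjusted p = 0.24), the early-response transcription factor Egr1 (1.58 ± 0.45) (adjusted p = 0.19), Il1b (1.51 ± 0.35) (adjusted p = 0.083) and the nuclear RNA Malat1 (1.44 ± 0.38) (adjusted p = 0.06), which were among the 8 highest genes. The matrix, endothelial and MHC class II lists did not shift (camera adjusted p = 0.73, 0.47 and 0.79). In all, 1421 genes changed, 577 higher and 844 lower, and 29 by at least 2-fold. Groups did not overlap in 1219 of them and 19.2% of all genes (5.71% by chance). The count was 899 without juvenile MV replicate 1 and 651 without replicate 3, and 27 with the spread estimated from these 2 groups alone, of which Flcn, Fnip1, Tubb4b, Camp and Ngp are named here. Leaving out single arrays ended other calls (adjusted p up to 0.12): Ngp without any of juvenile control replicates 1 to 3 or MV replicates 1 to 3, Nr1d2 without control replicate 2 or MV replicates 1 or 2, Dbp without control replicates 2 or 3 or MV replicates 1 or 2, Per3 without MV replicates 1 or 2, Egr1 without control replicate 2 or MV replicate 1, Hspa1a without control replicate 4 or MV replicate 1, Malat1 without control replicate 1, and Mcm6 without control replicate 1 or MV replicate 3. The cell cycle list ended without juvenile control replicate 1 (adjusted p = 0.13).

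In adults, MV alone (4 arrays against 4) coincided with high Xist. Glucocorticoid-responsive genes were higher and type 1 genes lower. Of the glucocorticoid and metallothionein genes, 13 of 16 rose and 3 did not pass (13 and 0 adjusted within the list, median 1.08, camera adjusted p = 4.5e-12, 0.17 with estimated correlation). They included Zbtb16 (2.31 ± 0.28), Mt2 (1.59 ± 0.25) and Klf9 (0.95 ± 0.15). The coagulation initiator F3 (1.42 ± 0.15) and the urokinase receptor Plaur (1.01 ± 0.14) rose among the adhesion and coagulation genes, of which 4 of 14 rose and 10 did not pass (3 and 0 adjusted within the list, median 0.13, camera adjusted p = 7.3e-04, 0.38 with estimated correlation). Among alveolar type 1 markers, from the cells that line most of the gas-exchange surface, 0 of 10 rose, 8 fell and 2 did not pass (0 and 9 adjusted within the list, median -0.32, camera adjusted p = 6.3e-04, 0.24 with estimated correlation). They included Igfbp2 (-1.35 ± 0.17), Aqp5 (-0.63 ± 0.09) and Ager (-0.60 ± 0.08). Of the extracellular matrix genes, 1 of 20 rose, 14 fell and 5 did not pass (1 and 14 adjusted within the list, median -0.47, camera adjusted p = 7.3e-04, 0.58 with estimated correlation). They included Col6a3 (-0.83 ± 0.13), Loxl1 (-0.63 ± 0.09) and Sparc (-0.49 ± 0.07). Surfactant and type 2 markers did not shift as a list (camera adjusted p = 0.46), while 5 of 13 fell, such as Etv5 (-0.82 ± 0.09) and Lpcat1 (-0.78 ± 0.08), and 2 rose (5 and 2 adjusted within the list). The transcription factor Klf2 (-1.83 ± 0.25), a marker of laminar flow in endothelium, was among the 4 lowest genes with Gp1bb (-1.83 ± 0.27) and Misp3 (-1.48 ± 0.15), and 1 control array had a Klf2 intensity of 2056 (others 838 to 1039).

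Of the cytokine and chemokine genes, 5 of 19 rose, 1 fell and 13 did not pass (5 and 1 adjusted within the list, median 0.23, camera adjusted p = 1.3e-04, 0.44 with estimated correlation). They included the chemokines Ccl17 (1.11 ± 0.20) and Cxcl1 (0.76 ± 0.19), which rose, and Il1b (-1.07 ± 0.32), which fell. Of the TLR and NF-kB genes, 6 of 21 rose and 15 did not pass (7 and 0 adjusted within the list, median 0.08, camera adjusted p = 0.0029, 0.58 with estimated correlation). They included the inhibitor Nfkbia (0.86 ± 0.09) and Cd14 (0.73 ± 0.11), and the median was 0.035 without MV replicate 3, 0.17 without MV replicate 4 and 0.038 without control replicate 1. Other high genes were the costimulatory ligand Tnfsf9 (1.83 ± 0.22), Pmvk (1.83 ± 0.26) of the mevalonate pathway, Mtm1 (1.72 ± 0.42), Hspa1b (3.43 ± 0.79), Hspa1a (3.06 ± 0.83) and Clca1 (3.26 ± 0.75). Xist (3.49 ± 0.83) was the highest gene and Eif2s3y (-2.41 ± 0.59) the lowest, as all 4 MV and no control arrays had high Xist. In all, 4123 genes changed, 938 higher and 3185 lower, and 87 by at least 2-fold. Groups did not overlap in 3274 of them and 30.5% of all genes (2.86% by chance). Lower calls were 77.2% of all, and 58.5% after quantile normalization. With the Xist pattern as a term 1712 genes passed and the cytokine median was 0.13 (0.51 with a pseudocount of 1). The term ended the matrix (adjusted p = 0.11, median -0.25), adhesion (0.11, -0.00031) and TLR (0.21, -0.054) list calls. Calls of Xist, Eif2s3y, Clca1, Hspa1a, Hspa1b, Ccl17 and Cxcl1 ended too. The median SE rose from 0.085 to 0.111 and 8 genes passed for the term, so lower precision may have ended calls. The Il1b call also ended without adult control replicate 3 (adjusted p = 0.065) or 4 (adjusted p = 0.068).

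Inhaled LPS in juveniles (4 arrays against 4) raised chemokines and interferon-stimulated genes. The T cell chemokine Cxcl10 went from an intensity of 19.5 ± 2.85 (SD, n = 4) to 4467 ± 1131 (SD, n = 4), a change of 6.41 ± 0.22. Of the inflammatory cytokines and chemokines, 17 of 19 rose and 2 did not pass (18 and 0 adjusted within the list, median 3.25, camera adjusted p = 3.0e-36). The median was 2.16 without the filter. They included the neutrophil chemokines Cxcl1 (5.33 ± 0.19), Cxcl5 (4.92 ± 0.18), Cxcl2 (4.58 ± 0.18) and Cxcl3 (4.44 ± 0.14). Of the TLR and NF-kB genes, 18 of 21 rose and 3 did not pass (19 and 0 adjusted within the list, median 2.17, camera adjusted p = 6.1e-37). They included Cd14 (4.63 ± 0.11), Nfkbie (2.86 ± 0.12) and Tlr2 (2.86 ± 0.12), and the median was 1.43 with the mean over probe sets. Of the interferon-stimulated genes, 22 of 22 rose (22 and 0 adjusted within the list, median 2.09, camera adjusted p = 1.8e-35). They included Ifit1 (3.69 ± 0.20) and Ifit3 (3.22 ± 0.20). The acute phase protein Saa3 (6.04 ± 0.30) and the metalloreductase Steap4 (4.37 ± 0.21) completed the 8 highest genes, and the metallothionein Mt2 (4.31 ± 0.25) rose as well. Among leukocyte adhesion genes, 8 of 14 rose, 1 fell and 5 did not pass (10 and 1 adjusted within the list, median 0.82, camera adjusted p = 1.6e-06, 0.16 with estimated correlation). They included Icam1 (1.83 ± 0.09) and Selp (1.62 ± 0.16), which bind leukocytes to the vessel wall. Of the neutrophil markers, 8 of 14 rose and 6 did not pass (9 and 0 adjusted within the list, median 0.94, camera adjusted p = 4.0e-05, 0.52 with estimated correlation). They included Fpr2 (1.74 ± 0.22), a receptor for formyl peptides.

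Among cell cycle genes, 0 of 24 rose, 21 fell and 3 did not pass (0 and 22 adjusted within the list, median -0.80, camera adjusted p = 6.7e-10, 0.5 with estimated correlation). They included Rrm2 (-1.64 ± 0.30) and Mcm5 (-1.08 ± 0.21). The epithelial transcription factor Elf5 (-1.85 ± 0.09) was among the 4 lowest genes, with Bex2 (-2.34 ± 0.15), Cckar (-1.84 ± 0.08) and Ppp1r14c (-1.68 ± 0.10). Of the surfactant and type 2 markers, 1 of 13 rose, 4 fell and 8 did not pass (1 and 4 adjusted within the list, median -0.02, camera adjusted p = 0.21). They included the transcription factor Etv5 (-1.53 ± 0.09) and the lipid transporter Abca3 (-0.86 ± 0.12), which fell, and the collectin Sftpd (0.56 ± 0.08), which rose. Of the early-response genes, 14 of 28 rose, 3 fell and 11 did not pass (15 and 3 adjusted within the list, median 0.45, camera adjusted p = 4.0e-05, 0.61 with estimated correlation). They included Junb (2.38 ± 0.26) and Ier3 (1.74 ± 0.19), which rose, and Ccn2 (-1.31 ± 0.19), which fell. In all, 2999 genes changed, 1254 higher and 1745 lower, and 301 by at least 2-fold. In 2280 of them the groups did not overlap (chance share 2.86% per gene tested). No gene named here lost its call when any 1 array was left out.

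In adults, LPS (4 arrays against 4) also raised chemokine and interferon-stimulated genes. Cxcl10 went from 30.4 ± 14.4 (SD, n = 4) to 2267 ± 545 (SD, n = 4) intensity units, a change of 5.19 ± 0.22. Of the cytokine and chemokine genes, 19 of 19 rose (19 and 0 adjusted within the list, median 2.58, camera adjusted p = 1.8e-32). They included Cxcl1 (5.19 ± 0.19), Cxcl5 (5.05 ± 0.18), Cxcl2 (5.05 ± 0.18), Cxcl3 (4.74 ± 0.14) and Ccl20 (4.69 ± 0.11). These and Saa3 (5.21 ± 0.30) and the anion exchanger Slc26a4 (4.45 ± 0.15) were the rest of the 8 highest genes. Of the TLR and NF-kB genes, 20 of 21 rose and 1 did not pass (20 and 0 adjusted within the list, median 1.93, camera adjusted p = 5.1e-31). They included Cd14 (3.98 ± 0.11) and Tnfaip2 (3.41 ± 0.15). Of the interferon-stimulated genes, 21 of 22 rose and 1 did not pass (21 and 0 adjusted within the list, median 1.11, camera adjusted p = 4.1e-15, 0.19 with estimated correlation). They included Ifit1 (2.89 ± 0.20) and Irf1 (1.33 ± 0.14). Among adhesion genes 10 of 14 rose and 4 did not pass (11 and 0 adjusted within the list, median 0.95, camera adjusted p = 2.5e-10). They included Selp (2.23 ± 0.16) and Icam1 (1.45 ± 0.09). Of the neutrophil markers, 11 of 14 rose and 3 did not pass (12 and 0 adjusted within the list, median 1.24, camera adjusted p = 1.0e-05, 0.49 with estimated correlation). They included Il1r2 (2.94 ± 0.29) and Trem1 (2.13 ± 0.22). Among glucocorticoid and metallothionein genes 14 of 16 rose and 2 did not pass (14 and 0 adjusted within the list, median 1.31, camera adjusted p = 2.1e-11, 0.19 with estimated correlation). They included Mt2 (4.00 ± 0.25) and Mt1 (2.91 ± 0.23).

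Among alveolar type 1 markers 0 of 10 rose, 7 fell and 3 did not pass (1 and 8 adjusted within the list, median -0.27, camera adjusted p = 0.03, 0.53 with estimated correlation). They included Aqp5 (-0.83 ± 0.09) and Igfbp2 (-0.70 ± 0.17). Of the type 2 markers, 2 of 13 rose, 5 fell and 6 did not pass (2 and 5 adjusted within the list, median -0.16, camera adjusted p = 0.11). They included Etv5 (-2.16 ± 0.09). The other 3 of the 4 lowest genes were Cckar (-2.76 ± 0.08), Elf5 (-2.31 ± 0.09) and Irs1 (-1.62 ± 0.16), an adaptor of insulin signalling. Of the matrix genes, 1 of 20 rose, 11 fell and 8 did not pass (1 and 11 adjusted within the list, median -0.35, camera adjusted p = 0.027, 0.74 with estimated correlation). They included Eln (-0.90 ± 0.18) and Col6a3 (-0.69 ± 0.13). Among early-response genes 17 of 28 rose, 1 fell and 10 did not pass (17 and 3 adjusted within the list, median 0.60, camera adjusted p = 2.0e-06, 0.55 with estimated correlation). They included Gadd45g (2.40 ± 0.21) and Maff (1.97 ± 0.21). The cell cycle list did not shift (camera adjusted p = 0.71). In all, 4706 genes changed, 1694 higher and 3012 lower, and 324 by at least 2-fold. Groups did not overlap in 3856 of them and 34.6% of all genes (2.86% by chance). No gene named here lost its call when any 1 of the 8 arrays was left out, and the matrix list lost it without adult LPS replicate 3 (adjusted p = 0.057) and with the mean over probe sets (adjusted p = 0.13, median -0.25). Adult LPS replicate 1 stood apart, with a mean log2 of 10.11 for neutrophil markers (others 9.01 to 9.14) and 8.44 for interferon-stimulated genes (8.90 to 8.93).

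**Figure D2:**
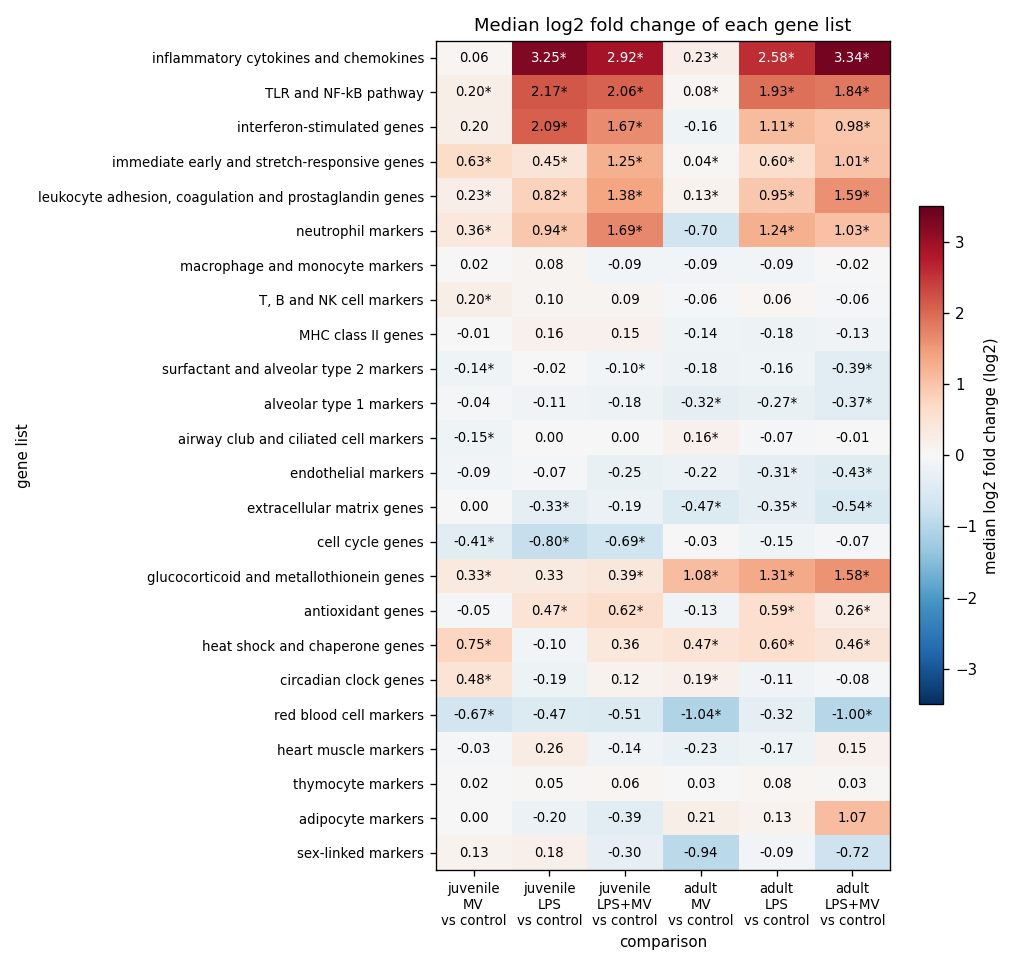
Median log2 fold change of each of the 24 gene lists (vertical axis) in the 6 comparisons of a treated group with its control (horizontal axis), with a star where the camera adjusted p was under 0.05 with the preset correlation. Medians of cytokine and chemokine genes lie between 2.58 and 3.34 in the 4 comparisons with LPS after filtering and at 0.06 and 0.23 with ventilation alone.

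With LPS and ventilation combined in juveniles (3 arrays against 4), cytokine, early-response and neutrophil genes rose. Of the cytokine and chemokine genes, 19 of 19 rose (19 and 0 adjusted within the list, median 2.92, camera adjusted p = 7.7e-38). Among the 8 highest genes were Cxcl1 (5.54 ± 0.21), Cxcl2 (5.21 ± 0.20), Il6 (4.56 ± 0.40) and Il1b (4.50 ± 0.35). Cxcl10 (6.39 ± 0.24), Saa3 (5.16 ± 0.33), the oxysterol enzyme Ch25h (4.46 ± 0.26) and Mt2 (4.28 ± 0.27) completed that set. Of the TLR and NF-kB genes, 20 of 21 rose and 1 did not pass (20 and 0 adjusted within the list, median 2.06, camera adjusted p = 4.5e-38). They included Cd14 (4.27 ± 0.12) and Tnfaip3 (3.77 ± 0.15). Among early-response genes 21 of 28 rose, 2 fell and 5 did not pass (22 and 2 adjusted within the list, median 1.25, camera adjusted p = 5.4e-16, 0.19 with estimated correlation). They included Junb (3.39 ± 0.28), Zfp36 (3.32 ± 0.26) and Myc (1.38 ± 0.13). Of the neutrophil markers, 14 of 14 rose (14 and 0 adjusted within the list, median 1.69, camera adjusted p = 5.5e-11, 0.21 with estimated correlation). They included Camp (1.53 ± 0.21) and Fpr2 (1.79 ± 0.24). Among interferon-stimulated genes 21 of 22 rose and 1 did not pass (21 and 0 adjusted within the list, median 1.67, camera adjusted p = 7.5e-25). They included Ifit1 (3.96 ± 0.22) and Irf1 (2.16 ± 0.15). Of the adhesion and coagulation genes, 11 of 14 rose, 1 fell and 2 did not pass (11 and 1 adjusted within the list, median 1.38, camera adjusted p = 4.0e-12). They included Selp (2.36 ± 0.18) and Plaur (1.81 ± 0.15).

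The type 2 genes Etv5 (-2.23 ± 0.10), the lowest gene of all, and Lpcat1 (-0.86 ± 0.09), an enzyme of surfactant lipid synthesis, fell. Elf5 (-2.02 ± 0.09), Cckar (-1.75 ± 0.09) and Txnip (-1.68 ± 0.17), an inhibitor of thioredoxin, were the next lowest. Of the cell cycle genes, 0 of 24 rose, 17 fell and 7 did not pass (0 and 21 adjusted within the list, median -0.69, camera adjusted p = 1.1e-04, 0.71 with estimated correlation). They included Mcm6 (-1.05 ± 0.16) and Mcm7 (-0.92 ± 0.14). Among glucocorticoid and metallothionein genes 6 of 16 rose, 1 fell and 9 did not pass (7 and 1 adjusted within the list, median 0.39, camera adjusted p = 1.1e-04, 0.54 with estimated correlation). They included Cebpd (2.76 ± 0.26) and Mt1 (3.34 ± 0.25). Without LPS+MV replicate 3 the median was -0.45 for cell cycle genes, which had -0.33 without control replicate 1. For glucocorticoid genes it was 0.16 and 0.65 without control replicates 3 and 4. In all, 4099 genes changed, 1416 higher and 2683 lower, and 339 by at least 2-fold. Groups did not overlap in 3350 of them and 32.2% of all genes (5.71% by chance). With the spread estimated from these 2 groups alone the count was 2659.

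In adults the combination (4 arrays against 4) changed more genes than any other comparison in the fit without the Xist pattern, but not with that pattern as a term. The neutrophil chemokines Cxcl1 (6.20 ± 0.19), Cxcl2 (5.68 ± 0.18) and Cxcl3 (4.73 ± 0.14), Cxcl10 (5.21 ± 0.22), Ccl20 (4.78 ± 0.11), Il6 (4.6 ± 0.37), Saa3 (4.86 ± 0.30) and Ch25h (4.51 ± 0.24) were the 8 highest, and of all cytokine and chemokine genes 19 of 19 rose (19 and 0 adjusted within the list, median 3.34, camera adjusted p = 6.2e-33). Of the TLR and NF-kB genes, 20 of 21 rose and 1 did not pass (21 and 0 adjusted within the list, median 1.84, camera adjusted p = 7.4e-30). They included Cd14 (3.94 ± 0.11) and Tnfaip3 (3.29 ± 0.14). Among early-response genes 18 of 28 rose, 3 fell and 7 did not pass (18 and 3 adjusted within the list, median 1.01, camera adjusted p = 1.7e-09, 0.39 with estimated correlation). They included Myc (1.90 ± 0.12), Egr2 (1.86 ± 0.15) and Gadd45a (1.67 ± 0.15). Of the adhesion and coagulation genes, 12 of 14 rose, 1 fell and 1 did not pass (12 and 1 adjusted within the list, median 1.59, camera adjusted p = 1.2e-11). They included Selp (2.65 ± 0.16) and Icam1 (1.57 ± 0.09). Among interferon-stimulated genes 16 of 22 rose and 6 did not pass (19 and 0 adjusted within the list, median 0.98, camera adjusted p = 3.0e-11, 0.3 with estimated correlation). They included Ifit1 (2.70 ± 0.20) and Irf1 (1.5 ± 0.14). Among glucocorticoid and metallothionein genes 13 of 16 rose and 3 did not pass (14 and 0 adjusted within the list, median 1.58, camera adjusted p = 2.6e-10, 0.22 with estimated correlation). They included Mt2 (3.96 ± 0.25) and Cebpd (2.83 ± 0.24).

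Among type 2 markers 1 of 13 rose, 7 fell and 5 did not pass (1 and 7 adjusted within the list, median -0.39, camera adjusted p = 0.021, 0.57 with estimated correlation). They included Etv5 (-2.75 ± 0.09), Lpcat1 (-1.07 ± 0.08) and the transcription factor Cebpa (-0.94 ± 0.11). Of the type 1 markers, 0 of 10 rose, 8 fell and 2 did not pass (0 and 8 adjusted within the list, median -0.37, camera adjusted p = 8.9e-04, 0.26 with estimated correlation). They included Aqp5 (-0.97 ± 0.09) and Ager (-0.63 ± 0.08). Among matrix genes 1 of 20 rose, 14 fell and 5 did not pass (1 and 15 adjusted within the list, median -0.54, camera adjusted p = 0.0012, 0.6 with estimated correlation). They included Eln (-1.17 ± 0.18). Cckar (-2.81 ± 0.08), Etv5, Elf5 (-2.22 ± 0.09) and Klf2 (-1.97 ± 0.25) were the 4 lowest genes. In all, 5512 genes changed, 1933 higher and 3579 lower, and 415 by at least 2-fold. Groups did not overlap in 4764 of them and 42.2% of all genes (2.86% by chance). Adult LPS+MV replicate 2 had the highest adipocyte score of all arrays (mean log2 10.4), with intensities of 2146 for Adipoq, 669 for Ucp1 and 1725 for the muscle gene Ckm.

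**Figure D3:**
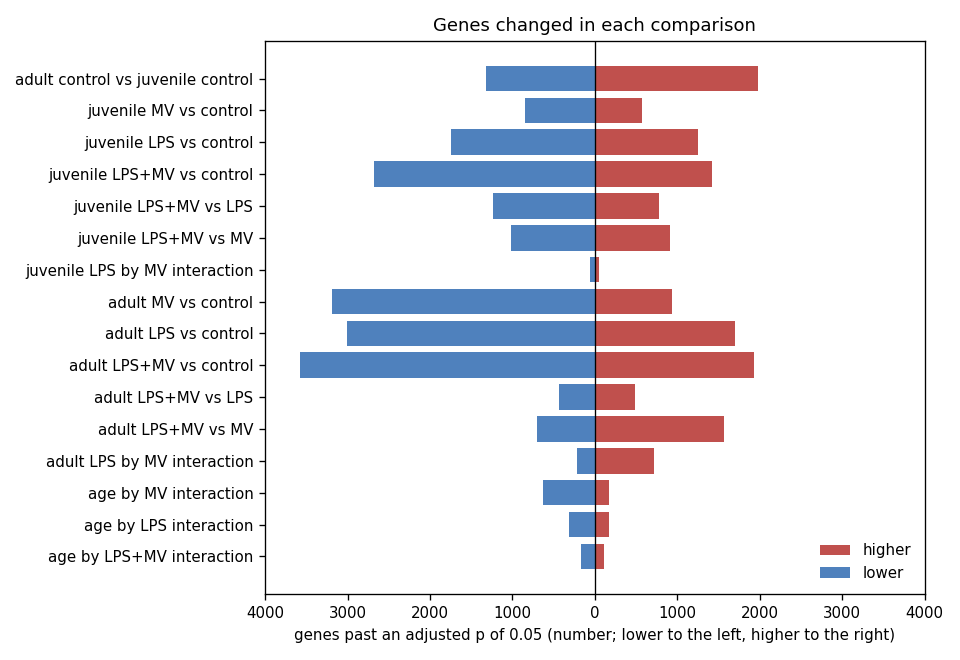
Number of genes past an adjusted p of 0.05 in each of the 16 comparisons, lower genes to the left and higher genes to the right. The adult LPS+MV comparison with control has the most genes in total, with 1933 higher and 3579 lower, in the fit without the Xist pattern as a term.

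Adding ventilation to LPS was read from LPS+MV against LPS alone, first in juveniles (3 arrays against 4). Among early-response genes 14 of 28 rose and 14 did not pass (22 and 0 adjusted within the list, median 0.76, camera adjusted p = 4.6e-13, 0.26 with estimated correlation). They included Zfp36 (1.78 ± 0.26), Ccn2 (1.34 ± 0.20) and Myc (0.88 ± 0.13). Of the adhesion and coagulation genes, 7 of 14 rose and 7 did not pass (8 and 0 adjusted within the list, median 0.54, camera adjusted p = 5.0e-06, 0.18 with estimated correlation). They included Plaur (1.22 ± 0.15) and F3 (0.94 ± 0.17). Il6 (2.37 ± 0.40) and Csf3 (1.21 ± 0.20), the granulocyte growth factor, rose while Cxcl3 (-0.83 ± 0.15) fell, and the cytokine list as a whole did not shift (camera adjusted p = 0.051). Among neutrophil markers 4 of 14 rose and 10 did not pass (4 and 0 adjusted within the list, median 0.71, camera adjusted p = 2.4e-05, 0.5 with estimated correlation). They included Ngp (2.75 ± 0.54) and Camp (1.42 ± 0.21). The highest genes were Hspa1b (2.87 ± 0.86), Hspa1a (2.86 ± 0.89), Ngp, Xist (2.60 ± 0.89) and G530011O06Rik (2.39 ± 0.27), and the lowest Slc26a4 (-1.88 ± 0.16), the acute phase protein Orm1 (-1.61 ± 0.21), Txnip (-1.31 ± 0.17), Noxo1 (-1.27 ± 0.09) and the alarmin Il33 (-1.13 ± 0.18). The type 2 genes Etv5 (-0.70 ± 0.10) and Lpcat1 (-0.45 ± 0.09) fell. Of the heat shock genes, 2 of 14 rose and 12 did not pass (2 and 0 adjusted within the list, median 0.40, camera adjusted p = 0.0063, 0.74 with estimated correlation). Without juvenile LPS+MV replicate 3, the other array with high heat shock genes (mean log2 11.4), the calls of Hspa1b (adjusted p = 0.19), Hspa1a (adjusted p = 0.25), Xist (adjusted p = 0.23) and the heat shock list (adjusted p = 0.38, median 0.016, against 0.65 without replicate 2) ended, and the early-response median was 0.45.

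In all, 2019 genes changed in this juvenile comparison, 782 higher and 1237 lower, and 75 by at least 2-fold. The count was 1277 without juvenile LPS+MV replicate 3, 1324 with the spread from these 2 groups alone and 1132 with the Xist pattern as a term. Xist also lost its call without any of the 4 juvenile LPS arrays or LPS+MV replicate 2, Hspa1b without LPS replicate 2, and Hspa1a without LPS replicates 2, 3 or 4 (adjusted p up to 0.22).

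In adults, ventilation after LPS (4 arrays against 4) raised Tnfsf9 (2.28 ± 0.22), Flcn (1.26 ± 0.11), Sowahb (1.5 ± 0.18) and Rsrp1 (1.70 ± 0.33). Of the cytokine and chemokine genes, 6 of 19 rose and 13 did not pass (9 and 1 adjusted within the list, median 0.43, camera adjusted p = 1.5e-06, 0.28 with estimated correlation). They included Il1rn (0.80 ± 0.12), the interleukin-1 receptor antagonist, and Csf2 (0.95 ± 0.15). Of the adhesion and coagulation genes, 3 of 14 rose, 1 fell and 10 did not pass (6 and 1 adjusted within the list, median 0.25, camera adjusted p = 0.0015, 0.41 with estimated correlation). They included Sele (0.93 ± 0.15), a selectin of activated endothelium, and Plaur (0.82 ± 0.14). Of the early-response genes, 5 of 28 rose, 1 fell and 22 did not pass (7 and 1 adjusted within the list, median 0.37, camera adjusted p = 1.3e-04, 0.62 with estimated correlation). The type 2 genes Etv5 (-0.59 ± 0.09) and Lpcat1 (-0.45 ± 0.08) and the endothelial gene Egfl7 (-0.93 ± 0.13) fell. The lowest genes were Eif2s3y (-1.99 ± 0.59), Wfdc17 (-1.46 ± 0.41), Tmem100 (-1.31 ± 0.21), Slc26a4 (-1.16 ± 0.15) and Slfn4 (-1.08 ± 0.31), and Ptgs2 (1.43 ± 0.44), the inducible prostaglandin synthase, completed the 5 highest. Lists of 2 other tissues passed, with no member alone (0 adjusted within the list). Heart muscle markers (median 0.31, camera adjusted p = 0.016, 0.79 with estimated correlation) lost the call without LPS+MV replicates 2 (adjusted p = 0.22, median 0.20) or 3 (adjusted p = 0.35, median 0.042) and with the Xist term (adjusted p = 0.067), and had a median of 0.62 without replicate 1. Adipocyte markers (median 0.78, camera adjusted p = 0.034, 0.63 with estimated correlation) lost it without LPS+MV replicate 2 (adjusted p = 0.41, median 0.20) or LPS replicate 3 (adjusted p = 0.054), and under 5 other settings (adjusted p up to 0.46). In all, 922 genes changed, 483 higher and 439 lower, and 21 by at least 2-fold, and lower calls were 47.6% of all, against 57.6% after quantile normalization. The count was 541 without adult LPS replicate 2, 595 without adult LPS+MV replicate 3 and 246 with the Xist pattern as a term, which ended the calls of Eif2s3y, Ptgs2, Wfdc17 and Slfn4 (adjusted p from 0.069 to 0.66) and of the early-response (adjusted p = 0.077) and adhesion (adjusted p = 0.11) lists. Those 4 genes each lost the call without at least 5 of the 8 arrays as well (adjusted p up to 0.13).

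LPS+MV against ventilation alone asks what LPS adds in ventilated lungs. In juveniles (3 arrays against 3), the 5 highest genes were Cxcl10 (5.94 ± 0.26), Cxcl2 (5.15 ± 0.21), Cxcl1 (5.13 ± 0.22), Saa3 (4.82 ± 0.35) and Cxcl5 (4.14 ± 0.21). Of the cytokine and chemokine genes, 19 of 19 rose (19 and 0 adjusted within the list, median 2.82, camera adjusted p = 1.7e-47), and of the TLR and NF-kB genes 18 of 21 rose and 3 did not pass (18 and 0 adjusted within the list, median 2.0, camera adjusted p = 1.1e-41). Among interferon-stimulated genes 22 of 22 rose (22 and 0 adjusted within the list, median 1.51, camera adjusted p = 3.6e-31). The lowest genes were Elf5 (-2.04 ± 0.10), Etv5 (-1.97 ± 0.10), Dbp (-1.94 ± 0.59), the arrestin-domain gene Arrdc3 (-1.78 ± 0.21) and G0s2 (-1.70 ± 0.28), an inhibitor of lipolysis. In all, 1925 genes changed, 907 higher and 1018 lower, and 275 by at least 2-fold. With the spread from these 2 groups alone the count was 1045, and the Dbp call ended without replicates 1 or 2 of MV or of LPS+MV (adjusted p up to 0.15).

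In adults (4 arrays against 4) the highest genes were Cxcl1 (5.44 ± 0.19), Cxcl10 (5.30 ± 0.22), Cxcl2 (5.25 ± 0.18), Ccl20 (4.56 ± 0.11) and Cxcl5 (4.42 ± 0.18). Of the cytokine and chemokine genes, 19 of 19 rose (19 and 0 adjusted within the list, median 3.10, camera adjusted p = 2.0e-43), and of the TLR and NF-kB genes 21 of 21 rose (21 and 0 adjusted within the list, median 1.85, camera adjusted p = 2.0e-38). Cckar (-2.41 ± 0.08), Etv5 (-1.93 ± 0.09), Elf5 (-1.68 ± 0.09), Arrdc3 (-1.61 ± 0.18) and the chitinase-like gene Chil4 (-1.52 ± 0.50) were the lowest genes. In all, 2271 genes changed, 1572 higher and 699 lower, and 284 by at least 2-fold, and lower calls were 30.8% of all, against 57.2% after quantile normalization. The Chil4 call ended with the Xist pattern as a term (adjusted p = 0.061) and without adult MV replicates 1 or 4 or any of the 4 LPS+MV arrays (adjusted p up to 0.2).

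**Figure D4:**
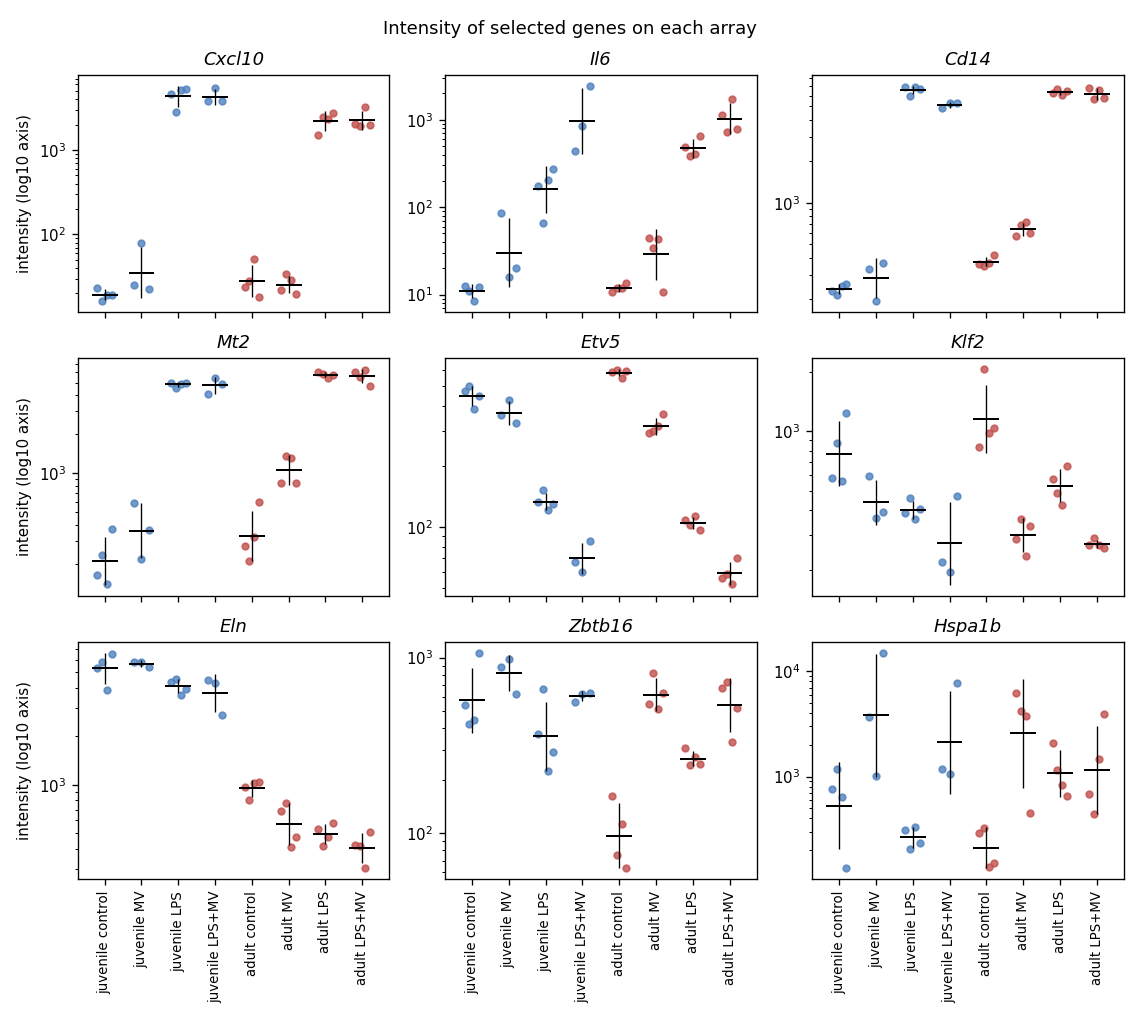
Intensity on a log10 axis of 9 genes on each of the 30 arrays, juveniles in blue and adults in red, with the geometric mean as a horizontal line and the SD of the log2 values as a vertical line. Cxcl10 reaches a mean of 4467 in juvenile LPS and 2267 in adult LPS arrays, against 19.5 and 30.4 in the controls of the same age.

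Whether ventilation and LPS together differ from the sum of both was tested as an interaction within each age. In juveniles Rnf144b (1.35 ± 0.17), Pde7b (1.37 ± 0.21), Rcan1 (1.33 ± 0.25), G530011O06Rik (1.81 ± 0.38) and the matrix protease Adamts4 (1.44 ± 0.33) were higher than the sum of the single changes on the log2 scale. Slc26a4 (-1.72 ± 0.23), Orm1 (-1.60 ± 0.30), Rgs2 (-1.41 ± 0.24), Zfp503 (-1.31 ± 0.27) and Armcx4 (-1.25 ± 0.30) were lower. No cell cycle gene passed alone (0 adjusted within the list), while the list lay above the sum (median 0.65, camera adjusted p = 2.4e-10, 0.5 with estimated correlation), with a median of 0.28 without juvenile control replicate 1. The interferon-stimulated list lay below the sum, with 0 higher and 0 lower (0 and 2 adjusted within the list, median -0.38, camera adjusted p = 3.0e-05, 0.58 with estimated correlation), and a median of -0.19 without juvenile MV replicate 2. In all, 98 genes passed, 44 higher and 54 lower, and the count was 63 without juvenile MV replicate 1, 54 without LPS+MV replicate 3, 157 after quantile normalization and 38 with the spread from these 4 groups alone. The call of G530011O06Rik ended without juvenile MV replicate 2 or LPS+MV replicate 3 and that of Zfp503 without LPS+MV replicate 3, and Adamts4 lost it without 6 and Armcx4 without 11 of the 14 arrays (adjusted p up to 0.14). With a pseudocount of 1, G530011O06Rik (adjusted p = 0.26), Adamts4 and Armcx4 lost it too, as did Zfp503, Adamts4 and Armcx4 with only the compared groups (adjusted p up to 0.13).

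In adults the glucocorticoid and metallothionein genes lay below the sum of the single changes, with 8 of 16 lower, 0 higher and 8 not passed (12 lower adjusted within the list, median -0.97, camera adjusted p = 5.9e-12, 0.17 with estimated correlation). Among them were Mt2 (-1.63 ± 0.36), Tsc22d3 (-1.32 ± 0.31) and Angptl4 (-1.30 ± 0.24). Ccl17 (-1.47 ± 0.29), Nfkbia (-0.85 ± 0.13) and Cd14 (-0.78 ± 0.16) were also below the sum, and Igfbp2 (1.11 ± 0.24) and the endothelial transcription factor Sox17 (1.08 ± 0.24) above it. The highest genes were Rsrp1 (1.57 ± 0.46), the membrane protease Mmp14 (1.38 ± 0.24), Ttn (1.35 ± 0.41), the antibody gene Igk (1.26 ± 0.33) and Rnd1 (1.2 ± 0.30), and the lowest Shmt1 (-2.0 ± 0.41), Mtm1 (-1.99 ± 0.60), the natriuretic peptide receptor Npr3 (-1.92 ± 0.30), Bzw2 (-1.81 ± 0.48) and Reg3g (-1.76 ± 0.55). In all, 937 genes passed, 720 higher and 217 lower, so that lower calls were 23.2%, against 53.2% after quantile normalization. The count was 477 without adult control replicate 2, 497 without MV replicate 3, 581 and 569 without LPS replicates 2 and 3, and 554 and 574 without LPS+MV replicates 2 and 4. Igk lost its call without LPS+MV replicate 4 and Bzw2 without control replicate 2, LPS replicate 2 or LPS+MV replicate 4 (adjusted p up to 0.062). Rsrp1, Ttn, Mtm1 and Reg3g lost it without at least 10 of the 16 arrays (adjusted p up to 0.1).

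Ventilation was then compared between ages, as adult minus juvenile log2 fold change. Controls enter all age differences: adult ones had higher Il1b, Ifitm6 and Ccr2 and lower Zbtb16 and Clca1. Il1b (-2.59 ± 0.47) and the neutrophil genes Camp (-1.49 ± 0.29) and Ngp (-2.68 ± 0.73) had a lower change in adults. Of the neutrophil markers 2 of 14 passed as lower and 0 as higher (5 and 0 adjusted within the list, median -0.85, camera adjusted p = 0.0062, 0.7 with estimated correlation), with a median of -0.48 without adult control replicate 4 (adjusted p = 0.055). Of the extracellular matrix genes 4 of 20 were lower and 0 higher (12 and 0 adjusted within the list, median -0.40, camera adjusted p = 8.7e-05, 0.5 with estimated correlation). The type 1 markers Igfbp2 (-1.45 ± 0.24) and Aqp5 (-0.67 ± 0.14) were lower. Of the glucocorticoid and metallothionein genes 3 of 16 were higher and 0 lower (9 and 1 adjusted within the list, median 0.78, camera adjusted p = 5.0e-06, 0.44 with estimated correlation). They included Zbtb16 (1.83 ± 0.41) and Angptl4 (1.11 ± 0.25). The highest genes were Clca1 (4.39 ± 1.11), the antimicrobial lectin Reg3g (2.55 ± 0.57), Mtm1 (2.22 ± 0.62), Gm9222 (2.13 ± 0.62) and Shmt1 (2.06 ± 0.42), and Ifitm6 (-2.35 ± 0.59), Malat1 (-2.19 ± 0.51) and Egr1 (-2.07 ± 0.61) were among the lowest with Ngp and Il1b. In all, 803 genes passed, 170 higher and 633 lower, so that lower calls were 78.8%, against 53.8% after quantile normalization.

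With the Xist pattern as a term 189 genes passed for this age difference in ventilation and the matrix median was -0.22, with array weights the glucocorticoid median was 0.41, and with the spread from these 4 groups alone 410. The count was 499 and 1307 without juvenile control replicates 1 and 4, 468 and 326 without juvenile MV replicates 1 and 2, and 508 without adult MV replicate 3. The Xist term ended the calls of Clca1, Reg3g, Mtm1, Gm9222, Ngp, Ifitm6 and Egr1 (adjusted p from 0.053 to 0.16). Clca1 also lost its call without juvenile MV replicate 1, Ifitm6 without juvenile MV replicates 1 or 2, and Ngp, Mtm1, Gm9222 and Egr1 without 5 to 11 of the 15 arrays (adjusted p up to 0.12).

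The change with LPS was compared between ages in the same way. Of the glucocorticoid and metallothionein genes 9 of 16 had a higher change in adults, 0 a lower one and 7 did not pass (10 and 0 adjusted within the list, median 0.95, camera adjusted p = 1.0e-09, 0.24 with estimated correlation). They included the clock gene Per1 (2.30 ± 0.42), the EGFR inhibitor Errfi1 (2.21 ± 0.38), Zbtb16 (1.83 ± 0.39) and Sgk1 (1.0 ± 0.18). Npr3 (2.30 ± 0.30) and Fam107a (1.99 ± 0.42) were the other 2 of the 5 highest genes. Interferon-stimulated genes had a lower change in adults, with 10 of 22 lower and 0 higher (20 and 0 adjusted within the list, median -0.81, camera adjusted p = 1.6e-14, 0.2 with estimated correlation). They included Ifit3 (-1.69 ± 0.29), Usp18 (-1.45 ± 0.24) and Ifit2 (-1.35 ± 0.25). Il1b (-1.75 ± 0.46), the nucleotide kinase Cmpk2 (-1.46 ± 0.28) and the acute phase gene Saa1 (-1.46 ± 0.24) were also lower. In all, 483 genes passed, 172 higher and 311 lower, and 825 passed without juvenile control replicate 4. The Il1b call ended without juvenile LPS replicates 1 or 3, adult control replicates 3 or 4, or adult LPS replicates 1 or 4 (adjusted p up to 0.071).

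For the combination, Zbtb16 (2.06 ± 0.41), Pdk4 (1.77 ± 0.43), Fam107a (1.69 ± 0.43), Npr3 (1.21 ± 0.32) and Cxcl3 (1.12 ± 0.21) had the highest change in adults relative to juveniles. The neutrophil genes Ngp (-2.85 ± 0.73) and Camp (-1.74 ± 0.29), Ifitm6 (-2.58 ± 0.59), Ccr2 (-2.09 ± 0.52) and the coagulation factor gene F13a1 (-1.96 ± 0.42) had the lowest. Of the neutrophil markers 2 of 14 were lower and 0 higher (2 and 0 adjusted within the list, median -0.99, camera adjusted p = 9.4e-04, 0.61 with estimated correlation). Of the interferon-stimulated genes 4 of 22 were lower and 0 higher (11 and 0 adjusted within the list, median -0.66, camera adjusted p = 1.0e-09, 0.38 with estimated correlation). They included Ifit3 (-1.41 ± 0.30). The type 1 marker Aqp5 (-0.74 ± 0.14) was lower. In all, 275 genes passed, 112 higher and 163 lower. The count ranged widely when arrays were left out: 95, 167 and 1136 without juvenile control replicates 1, 2 and 4, 167 without juvenile LPS+MV replicate 3, 464, 143 and 160 without adult control replicates 1, 3 and 4, and 171 without adult LPS+MV replicate 3, and it was 71 with the spread from these 4 groups alone. Zbtb16, Cxcl3, F13a1, Camp, Ifit3 and Aqp5 kept their calls without any 1 array, Ifitm6 lost it without juvenile control replicate 1, and Pdk4, Fam107a, Npr3, Ngp and Ccr2 lost it without 6 to 10 of the 15 arrays (adjusted p up to 0.094).

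Fold changes of the 2 ages were correlated across genes changed at either age, where genes are not independent replicates. For LPS, Pearson's r was 0.83 and Spearman's rho 0.70 over 5658 genes. Of 2047 genes changed at both ages, 895 were higher at both, against 162 expected of independent lists, and 1120 lower at both, against 402. For LPS+MV, r was 0.85 and rho 0.69 over 6766 genes, with 1068 genes higher at both ages, against 209 expected, and 1751 lower at both, against 734. For ventilation alone, r was 0.42 and rho 0.37 over 4821 genes, with 181 genes higher at both ages, against 41.4 expected, and 500 lower at both, against 205.

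LPS and ventilation were also compared within each age, where both share the same controls. In juveniles r across genes was 0.24, with a covariance of 0.0196, and unchanged groups simulated against those controls gave r = 0.46 and a covariance of 0.0059. In adults r was 0.45, with a covariance of 0.0491, against a simulated r of 0.50 and covariance of 0.00589. The covariance exceeded the simulated one by 0.0137 in juveniles and 0.0432 in adults. With the controls split between the comparisons, r averaged 0.13 (0.083 to 0.167) in juveniles and 0.40 (0.21 to 0.51) in adults.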

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

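The tests of the sex pattern in adult ventilation, of both explanations for the clock genes, and of LPS levels against the age difference without 1 control, were chosen after those results had been seen, the other tests before.

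Within groups of 4 arrays, 1 array stood apart in 7 of 222 groups tested. Chance marks about 1 in 20 such groups. For list scores (mean log2) adult LPS replicate 1 had 8.44 for interferon-stimulated genes, against 8.90 to 8.93 in the others, and 10.11 for neutrophil markers, against 9.01 to 9.14. Adult MV replicate 2 had a glucocorticoid score of 10.10 (others 9.76 to 9.81), adult LPS+MV replicate 2 a red cell score of 8.11 (8.36 to 8.38), and adult LPS replicate 2 a thymocyte score of 5.80 (5.66 to 5.67). Cxcl10 had an intensity of 3240.2 on adult LPS+MV replicate 3 (1920.2 to 2033.4), and Klf2 of 2056 on adult control replicate 2 (838 to 1039).

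Responses differed by an interaction test in 98 genes (LPS with ventilation, juveniles), 937 (the same, adults), 803 (age with ventilation), 483 (age with LPS) and 275 (age with LPS+MV). Median log2 differences between ages of lists that passed were, with ventilation, 0.15 for cytokines, -0.51 for early-response genes, -0.85 for neutrophil, -0.28 for type 1 and 0.19 for airway markers, -0.40 for matrix, 0.35 for cell cycle and 0.78 for glucocorticoid genes. With LPS they were -0.81 for interferon-stimulated genes, 0.22 for adhesion, -0.29 for MHC class II, 0.67 for cell cycle, 0.95 for glucocorticoid and 0.63 for heat shock genes. With LPS+MV they were 0.38 for cytokines, -0.66 for interferon-stimulated genes, -0.99 for neutrophil markers, -0.25 for MHC class II, -0.20 for type 1, -0.20 for endothelial and -0.34 for matrix genes, 0.48 for cell cycle, 0.65 for glucocorticoid and -0.20 for antioxidant genes, and 1.46 for adipocyte markers. None of these 25 passed with an estimated correlation.

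Several moved when 1 array was left out. With ventilation, the early-response call ended without 9 of 15 arrays and with 5 other settings (adjusted p up to 0.79), and its median was -0.24 without juvenile MV replicate 3 and -0.81 without 2. The cytokine call ended without juvenile MV replicate 2 (adjusted p = 0.1) or adult MV replicate 3 (adjusted p = 0.18), and with 5 other settings (adjusted p up to 0.43), and the median was 0.23 without juvenile MV replicate 1. Without adult control replicate 4 the neutrophil call ended (median -0.48, adjusted p = 0.055). The cell cycle median was 0.057 without juvenile control replicate 1, 0.54 without control replicate 4 and 0.22 without juvenile MV replicate 3. With LPS, the MHC class II call ended without adult LPS replicate 1 (adjusted p = 0.051), and the cell cycle median was 0.39 without juvenile control replicate 1. With LPS+MV, the antioxidant (adjusted p = 0.3, median -0.11) and MHC class II (adjusted p = 0.068, median -0.077) calls ended without juvenile LPS+MV replicate 3, the endothelial call without juvenile control replicate 3 (adjusted p = 0.093, median -0.12), the glucocorticoid call without juvenile control replicate 4 (adjusted p = 0.051) and the cytokine call without juvenile LPS+MV replicate 1 (adjusted p = 0.052), where the antioxidant median was -0.31. The cell cycle median was 0.20 without juvenile control replicate 1, and the adipocyte median 0.93 without adult LPS+MV replicate 2.

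Genes with the largest log2 differences between ages with ventilation were Clca1 (4.39), Reg3g (2.55), Mtm1 (2.22), Gm9222 (2.13), Shmt1 (2.06), Ngp (-2.68), Il1b (-2.59), Ifitm6 (-2.35), Malat1 (-2.19) and Egr1 (-2.07). With LPS they were Per1 (2.30), Npr3 (2.30), Errfi1 (2.21), Fam107a (1.99), Zbtb16 (1.83), Il1b (-1.75), Ifit3 (-1.69), Cmpk2 (-1.46), Saa1 (-1.46) and Usp18 (-1.45). With LPS+MV they were Zbtb16 (2.06), Pdk4 (1.77), Fam107a (1.70), Npr3 (1.21), Cxcl3 (1.12), Ngp (-2.85), Ifitm6 (-2.58), Ccr2 (-2.09), F13a1 (-1.96) and Camp (-1.74). Of 2655 probe sets without a single gene symbol, which the comparisons leave out, LPS changed 240 in juveniles (123 higher) and 510 in adults (246 higher).

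Chance is argued against, not excluded, where no other split, or at most 1 of 99 for an interaction, called as many genes. That held for the controls of both ages (3301 genes, highest other split 2116), juvenile MV (1421, 1023), LPS (2999, 313) and LPS+MV (4099, 3189) against control, and LPS+MV against LPS (2019, 477). In adults it held for MV (4123, 21), LPS (4706, 7) and LPS+MV (5512, 80) against control, and LPS+MV against LPS (922, 17) and MV (2271, 97). It held for LPS with ventilation in juveniles (98, 172; 2 of 100 as large) and adults (937, 86), and for age with ventilation (803, 6), LPS (483, 5) and LPS+MV (275, 572; 2 of 100). For the 2 with 2 of 100, 1 regrouping called more and why was not tested. Shares were unadjusted. For juvenile LPS+MV against MV (1925, 40) the splits are too few for a share under 0.05.

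In adult MV against control, 77.2% of the 4123 called genes were lower. Sex pattern and ventilation cannot be told apart, as all 4 MV arrays and no control had high Xist. With the Xist term, set by other groups, fold changes kept a slope of 0.872 (jackknife SD 0.0652) on those without. The term assumes 1 sex effect for all, so one in adults or ventilated animals alone stays open. Of called genes 4119 kept their sign and 1663 passed. A single dim array is argued against, since 71.7% were lower without adult MV replicate 3. Scaling cannot be told apart from a change in the tissue, with 58.5% lower after quantile normalization, and ventilation itself is untested.

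In juvenile MV the median of the clock genes was 0.48. The array with high heat shock genes as the cause is argued against, since the median was 0.57 without it (jackknife SD 0.133 over arrays). Another time of day at collection, which may raise Dbp and lower Arntl, cannot be told apart from an effect of ventilation, because the median of Arntl, Npas2 and Clock was -0.29 and their mean -0.21 (SE 0.195).

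Glucocorticoid genes had a larger change with LPS in adults, with a median difference of 0.95 between ages. The sex pattern is argued against, as the difference was 1.02 with the Xist term. A higher level reached with LPS in adults cannot be told apart from a difference between the controls. Adult LPS exceeded juvenile LPS by 0.35 (jackknife SD 0.0799), under 0.5 of the age difference (0.48) with all arrays, but within its spread of that share (0.40) without juvenile control replicate 4. The controls differed by -0.62 (jackknife SD 0.367), and by -0.28 without that array. Whether juvenile control replicate 4, with the highest control levels, likely contributed cannot be settled: without it the difference was 0.79 (jackknife SD 0.33). Stress at collection is not in the labels, and age itself stays open as untested.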

How the results depend on the processing

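The Xist term and the 4 or 2 arrays left out together were chosen after the data were seen, all other alternatives before. Of 610 named gene values, 431 kept direction and side of the threshold under every alternative, and of 159 list calls 104 did, apart from estimated correlation and fry. The cause of the changes below was not tested, except that leaving out arrays or groups also lowers the number of samples.

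With array weights the counts were 2616 for juvenile MV (1421 without), 3433 for juvenile LPS+MV against LPS (2019), 4724 against MV (1925), 508 for LPS with ventilation in juveniles (98) and 1604 in adults (937), 1776 for adult LPS+MV against LPS (922), and 2075, 943 and 1723 for age with ventilation (803), LPS (483) and LPS+MV (275). With only the compared groups they were 27 for juvenile MV, 2659 for juvenile LPS+MV (4099), 1324 against LPS, 1045 against MV, 38 for LPS with ventilation in juveniles, 410 for age with ventilation and 71 for age with LPS+MV. The Xist term gave 1132 for juvenile LPS+MV against LPS, 1712 for adult MV (4123), 246 for adult LPS+MV against LPS and 189 for age with ventilation. Without the 4 arrays juvenile MV gave 928 and LPS with ventilation in adults 489, and without the 2 heat shock arrays juvenile MV gave 788. Quantile normalization gave 157 for LPS with ventilation in juveniles, and it moved the median of all genes by at most -0.077, in adult LPS with ventilation. The replicate block gave 612 for age with LPS+MV. Arrays of different groups at 1 age that share a replicate number had a mean residual correlation of 0.0417 (16 of 43 pairs above 0.1), those with different numbers -0.0133, and the same numbers across the controls of both ages 0.143, and 9 of the 30 arrays correlated best with their own number, so numbers were not taken as pairs.

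Leaving out 1 array gave 651 to 1582 genes for juvenile MV, 1277 to 1769 for juvenile LPS+MV against LPS, 54 to 109 for LPS with ventilation in juveniles and 477 to 982 in adults, 541 to 948 for adult LPS+MV against LPS, 326 to 1307 for age with ventilation, 332 to 825 for age with LPS and 95 to 1136 for age with LPS+MV. Counts of the other 8 comparisons stayed within 1.5 times.

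With the correlation estimated, 23 of the 159 list calls held. The direction of the list test reversed for the T, B and NK cell list in juvenile LPS with ventilation without juvenile MV replicate 2 (0.022, with -0.50 the lowest over single arrays left out). Medians of 8 other lists that lost their call also turned in sign while the test kept its direction: in adult MV with the Xist term TLR (-0.054), early-response (-0.066), adhesion (-0.00031) and heat shock genes (-0.0057), and early-response genes also without MV replicate 2 (-0.031). They were also, in juvenile LPS+MV against LPS without LPS+MV replicate 3 antioxidant (-0.0079) and clock genes (-0.043), in juvenile MV without MV replicate 2 T, B and NK cell markers (-0.036), and in juvenile LPS with ventilation without LPS+MV replicate 3 early-response genes (-0.071). Leaving out 1 array moved the medians of 58 of the 159 lists by over 1.5 times, and any alternative 88. Under the Xist term, which stands for the same signal, the sign reversed for Xist (-0.08), Eif2s3y (0.12) and Uty (0.36) in adult MV and for Xist (-0.18) and Eif2s3y (0.13) in adult LPS+MV. With only the compared groups 17 genes named above lost their call in juvenile MV (adjusted p up to 0.2), 7 in age with LPS+MV (up to 0.15), Egr1 and Angptl4 in age with ventilation, Igk and Ttn in adult LPS with ventilation, Chil4 in adult and Dbp in juvenile LPS+MV against MV.

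Settings other than single arrays also moved medians given above by over 1.5 times or ended their calls. With a pseudocount of 1 they were 1.45 for neutrophil and 0.71 for T, B and NK cell markers between controls, 1.43 and 0.54 for neutrophil markers in juvenile LPS and MV, and -1.51 for them in age with LPS+MV, where they were -0.60 without the filter. With the mean over probe sets they were 0.31 for antioxidant genes in juvenile LPS, 0.30 for clock genes in juvenile MV and 0.047 for TLR genes in adult MV. Array weights gave 0.55 for neutrophil markers in juvenile MV and ended the heat shock calls in juvenile MV (0.19) and LPS+MV against LPS (0.089). Quantile normalization gave 0.20 for adhesion and 0.16 for TLR genes in adult MV. The Xist term gave -0.36 for matrix genes in adult LPS+MV, 0.28 for cytokines, 0.16 for adhesion and 0.12 for early-response genes in adult LPS+MV against LPS, and 0.059 for heat shock genes in juvenile LPS+MV against LPS, where that call ended.

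Between ages, r for LPS over all genes was 0.80 (0.83 over changed genes). With split controls, r between LPS and ventilation was 0.13 in juveniles (0.24) and 0.40 in adults (0.45), and with the Xist term 0.39 in adults. Leaving out 1 array gave 0.31 to 0.48 for MV, 0.81 to 0.84 for LPS and 0.81 to 0.87 for LPS+MV between ages, and 0.18 to 0.29 in juveniles and 0.43 to 0.48 in adults between LPS and ventilation. Signal over background limits genes near the array median, where the pseudocount of 32 shrinks fold changes.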

Other observations

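No value in this part is explained. Among antioxidant genes in juvenile LPS, 7 of 14 rose, 1 fell and 6 did not pass (8 and 1 adjusted within the list, median 0.47, camera adjusted p = 1.7e-05, 0.29 with estimated correlation), with Sod2 (2.26 ± 0.06), the mitochondrial superoxide dismutase, Gclc (1.84 ± 0.15), which makes glutathione, and Txnrd1 (1.24 ± 0.09). In adult LPS, 7 of 14 rose, 3 fell and 4 did not pass (7 and 3 adjusted within the list, median 0.59, camera adjusted p = 8.5e-05, 0.38 with estimated correlation), with Sod2 (1.92 ± 0.06), Gclc (2.24 ± 0.15) and Sod3 (-0.72 ± 0.13), the extracellular form. Antioxidant genes also passed in juvenile LPS+MV against MV, where 7 of 14 rose and 7 did not pass (10 and 0 adjusted within the list, median 0.46, camera adjusted p = 1.4e-11), with a median of 0.28 without LPS+MV replicate 3. Endothelial markers were lower in adult LPS+MV, where 0 of 18 rose, 12 fell and 6 did not pass (0 and 12 adjusted within the list, median -0.43, camera adjusted p = 0.0019, 0.55 with estimated correlation), with Egfl7 (-1.27 ± 0.13), Sox17 (-1.01 ± 0.17), Ramp2 (-0.81 ± 0.14) and the receptor Kdr (-0.78 ± 0.12). In juvenile LPS+MV 4 of 18 fell (4 adjusted within the list, camera adjusted p = 0.21), among them Egfl7 (-1.21 ± 0.14).

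Red cell markers were lower with ventilation in adults, where 0 of 4 rose and 4 fell (0 and 4 adjusted within the list, median -1.04, camera adjusted p = 0.011, 0.5 with estimated correlation), with the anion exchanger Slc4a1 (-1.35 ± 0.35) and Alas2 (-1.14 ± 0.20). Macrophage and monocyte markers did not shift in adult LPS (camera adjusted p = 0.91), where the scavenger receptor Marco (1.24 ± 0.15) rose and the cholesterol exporter Abcg1 (-0.54 ± 0.07) fell.

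Markers of tissue beside the lung were read on each array. Heart muscle markers had a mean log2 of 9.82 to 9.95 on juvenile LPS replicate 4 and adult LPS+MV replicates 2 and 3, the highest of all arrays. Against control, the list did not pass in adult LPS+MV (camera adjusted p = 0.32), while it passed against LPS. The same held for adipocyte markers. Their median and camera adjusted p against control were 1.07 and 0.069, with 0.03 and 0.59 for thymocyte and -0.72 and 0.67 for sex-linked markers. The last test cannot tell, as Xist opposes Y-linked genes. Dbp had an intensity of 729 and 816 on juvenile MV replicates 1 and 2 and of 566 on adult MV replicate 4, where Arntl was at 57.7, 65 and 75.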
